A study of Mus musculus with 4 samples.

How the data were processed

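Small RNA sequencing was done on extracellular vesicles released by C2C12 cells, an established mouse myoblast line. Per the labels' protocols, cells grew in a medium with 10% fetal bovine serum, and vesicles were collected by differential centrifugation. The labels put 2 libraries in a damaged group treated with hydrogen peroxide and 2 in a WT group whose treatment label is WT.

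The deposited file is a table of read counts per mature miRNA entry, with 1 column per library and no pooling of replicates. Per the submitters' processing notes, FastQC, BWA and featureCounts were used with the mouse build mm10. Per the file headers, featureCounts 2.0.1 counted reads over features of type miRNA grouped by their ID. The command in the header holds no strand option, no option to count multi-mapping reads and no option to count reads that overlap several features. The BWA version, the adapter trimming and the miRBase release are not given in the sources used here. Counting was therefore without strand, so reads from a miRNA and from an entry on the opposite strand cannot be told apart.

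The table holds 2110 rows for 1966 mature miRNA IDs. Of these IDs, 82 have several gene copies and take 226 rows, so identical mature sequences are counted in separate rows. For 27 mature miRNAs with 2 identical rows and at least 1000 counts, neither sharing bases with another entry, the smaller row held a median of 49.3% of the reads. For 26 of them it held 44.3% to 50%, and for miR-92a-3p 8.18%. Reads of identical rows cannot be assigned to a gene copy. A total of 106 rows share bases with a mature entry on the opposite strand. Rows were named by their position in the hairpins of GENCODE vM21, on the same strand and within 3 bases, with RefSeq synonyms of the same build; 2108 rows received a name, and the 2 without one held 0% of the counts in every library. The arm (5p or 3p) was taken from the position in the hairpin, and coordinates are those of the deposited table, 1-based on mm10. Mature sequences were taken from the GENCODE hairpin transcripts, at the place of the row in the hairpin, for the 2045 rows that lie in one.

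Library totals were 4577668 and 7638663 counts for WT replicates 1 and 2, and 6901394 and 7350345 for damaged replicates 1 and 2. A count of 0 allows up to 3 counts per library, or 0.393 to 0.655 CPM, the depth-scaled count. Shares of counts for single libraries carry exact (Clopper-Pearson) 95% intervals. Reads carried no molecular identifiers in the sources used here, so intervals and floors cover counting error only.

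The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM scaling and filterByExpr at a minimum count of 10, group as the only term, and Benjamini-Hochberg adjustment at 0.05. It tested 536 rows, which held 99.98% of the counts of each library. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values are TMM-scaled, and shares of counts are not. Gene lists with at least 3 tested rows were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01 on log2 CPM with a prior count of 2. camera was also run with the correlation estimated from the data. That version rests on 2 residual degrees of freedom, which leaves little power, so a list not called with it decides little. The preset correlation is not taken from these libraries, and its p can be too small if members vary together more than that. Members were also counted with p-values adjusted over the list alone. The design, the 17 lists, the rule for named miRNAs and the other settings, apart from those given as added later, were fixed before the data were examined. The rule named up to 10 higher and up to 10 lower rows past the threshold by smallest p, if both damaged libraries lay on the same side of both WT libraries, filled up to 5 where fewer than 10 passed in a direction, with such rows given as not passing. It added the 10 rows of highest mean CPM and the 2 most abundant members of each list. Further list members named in the text were chosen after their values were seen.

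The lists were muscle-enriched miRNAs, myogenic regulators, the let-7 family, the miR-30 family, the miR-17 polycistron with its paralogs, the Dlk1-Dio3 cluster, the X-linked cluster of miR-322 and miR-503, an oxidative stress, p53 and hypoxia list, tumour-suppressor miRNAs, oncomiRs and mesenchymal miRNAs. Markers of other sources were the lists blood cell and liver, epithelial, neural and endothelial. Entries suspected of being fragments of other RNA and the Sfmbt2 repeat cluster, whose copies are near-identical, were lists of their own. Lists overlap: the oncomiR list shares members with the polycistron list and with the list of oxidative stress, p53 and hypoxia, among others.

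The other settings were other scalings (RLE, upper quartile, library totals), no filter or a stricter filter of at least 10 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom, robust edgeR, the replicate number as a block, each library left out, suspected and repeat entries left out, gene copies summed, and the 5 most abundant rows left out. A correction for GC content, a sum over identical sequences, and leaving out each library with DESeq2 and limma-voom were added after seeing the data. The GC correction removed from each library a linear trend of log2 CPM on the GC content of the mature sequence, fitted on rows of at least 100 CPM. On simulated counts with a linear GC trend and no treatment effect, a slope of 3.71 before became -0.0422 after. That slope was taken on rows of at least 100 CPM, as in the fit, so a value near 0 was bound to result. Whether the correction also removes true changes, or holds for rows of lower count, was not tested.

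The test was checked on simulated counts for the damaged and WT comparison, with 536 rows, the real means, dispersions and library sizes, and 200 rows changed. edgeR recovered 41% of the 100 rows changed 2-fold and 70% of the 100 rows changed 4-fold. Among changed rows above 100 CPM it recovered 89.7% and 100%. Of 116 calls, 5 were false. In 20 simulated draws without any change, 6 gave a call, with at most 6 rows called. That is more draws than the adjusted p threshold allows when no row changes, so edgeR was too liberal there. The calls on the real data may thus hold more false ones than the threshold implies. With 200 rows changed, the share of false calls, 4.31%, stayed below the threshold. In the 20 draws without any change, camera called no list. Rows were drawn independently of each other, so these draws do not test list calls where members are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.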

Results

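The series asked how the miRNA cargo of extracellular vesicles differs between healthy and damaged muscle cells, with hydrogen peroxide as the damaging agent. C2C12 is a mouse myoblast line, and extracellular vesicles are membrane particles that cells release with RNA and protein inside. Each group held 2 libraries, with 4577668 and 7638663 counts for WT and 6901394 and 7350345 for damaged. Between 692 and 746 of the 2110 rows had at least 1 count in a library. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

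Vesicles of both groups were dominated by miR-206-3p, a miRNA made mainly in skeletal muscle. It took 28.6% of counts in WT replicate 1 (exact 95% interval 28.6 to 28.7), 32.6% in WT replicate 2 (32.6 to 32.6), 33.9% in damaged replicate 1 (33.9 to 34.0) and 36.6% in damaged replicate 2 (36.6 to 36.6). Its mean was 308580 ± 25851 CPM in WT and 349570 ± 11425 CPM in damaged (SD, n = 2), and the log2 fold change of 0.18 ± 0.11 (SE) did not pass the edgeR test (adjusted p = 0.334). miR-206-3p lies on chromosome 1 at 20679055 to 20679076 (mm10) in an exon of Gm28653, as does miR-133b-3p. The next most abundant row was miR-21a-5p, a miRNA common in proliferating and stressed cells, with 12.8% ± 1.30 of counts in WT and 10.1% ± 2.67 in damaged (SD, n = 2). Both copies of let-7c-5p, let-7b-5p, miR-27b-3p, miR-22-3p, miR-143-3p, miR-23a-3p and miR-378a-3p made up the rest of the 10 most abundant rows. Together these 10 rows held 67.55% ± 1.11 of counts in WT and 70.7% ± 1.46 in damaged (SD, n = 2). With 2 libraries against 2, an exact two-sided permutation test of shares cannot give a p below 0.33. Of these 10 rows, only miR-22-3p passed the edgeR test, with 14594 ± 471 CPM in WT and 29297 ± 6141 CPM in damaged (SD, n = 2; log2 fold change 1.01, adjusted p = 0.0305). Rows of identical sequence rank apart here. Summed, the sequence of miR-199a-3p and miR-199b-3p held 35700 CPM, above miR-27b-3p at 33300. It was lower in damaged (log2 fold change -0.84, adjusted p = 0.0393 by edgeR), but its single rows lost their calls after the GC correction (adjusted p = 0.0506). Summed let-7f-5p and let-7a-5p also ranked above miR-22-3p, and neither passed. In other settings on 4 libraries miR-23a-3p passed in 5 (lowest adjusted p = 2.95e-05), miR-27b-3p in 2 (0.00397) and miR-21a-5p in 1 (0.00605), each lowest with the replicate number as a block.

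Damage went with a shift in which miRNAs the vesicles carried. miR-34b-3p, of the p53-responsive miR-34 family, was 8.26-fold higher in damaged, and both copies of miR-133a-3p and miR-133b-3p, which are muscle miRNAs, were 2.17 to 2.33-fold higher. miR-15b-5p, miR-7a-5p, miR-25-3p, miR-322-5p and the miR-183, miR-96 and miR-182 trio were 2.04 to 2.87-fold lower. In all, edgeR called 51 of 536 tested rows, 22 higher and 29 lower, which stand for 20 and 24 distinct mature miRNA entries. Of these, 3 higher and 1 lower are entries suspected of being fragments of other RNA. miR-1843a-3p, also called higher, lies in an exon of Scarna3b. At an unadjusted p under 0.05 there were 165 rows, against 26.8 by chance. The number of calls rested on all 4 libraries: edgeR called 0 rows without WT replicate 1, WT replicate 2 or damaged replicate 1 (103, 124 and 144 rows at an unadjusted p under 0.05) and 30 without damaged replicate 2. On the same sets of 3 libraries, in that order, DESeq2 called 59, 73, 75 and 67 rows, and limma-voom 0, 0, 70 and 98, with 100 and 106 rows at an unadjusted p under 0.05 beside its counts of 0.

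The miRNA of smallest p was miR-34b-3p (AAUCACUAACUCCACUGCCAUC, MIMAT0004581), between annotated genes on the minus strand of chromosome 9 at 51103574 to 51103595. It rose from 219 ± 3.89 to 1807 ± 321 CPM (SD, n = 2), a log2 fold change of 3.05 ± 0.17 (SE, adjusted p = 0.00351 by edgeR). The rows of miR-133a-3p (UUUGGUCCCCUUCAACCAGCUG) lie in an intron of Mir133a-1hg on chromosome 18 at 10782913 to 10782934 and between genes on chromosome 2 at 180398437 to 180398458. They share 1 sequence, so their reads cannot be assigned to a locus, and their log2 fold changes were 1.14 and 1.12 (both adjusted p = 0.00914). miR-133b-3p, on chromosome 1 at 20682834 to 20682855, rose from 639 ± 34.3 to 1492 ± 125 CPM (SD, n = 2; adjusted p = 0.0107). miR-146a-5p, which dampens inflammatory signalling, rose from 1061 ± 171 to 2576 ± 176 CPM (SD, n = 2; adjusted p = 0.0161). let-7d-3p rose 2.76-fold while its partner arm let-7d-5p stood at 11543 ± 214 and 11120 ± 543 CPM (SD, n = 2). miR-320-5p rose 5.37-fold from 21.7 ± 8.82 CPM, miR-296-5p 3.04-fold and miR-328-3p 2.13-fold. miR-2137-3p, an entry in an intron of Zfp185 suspected of being a fragment of other RNA, rose 3.57-fold, and 2.13-fold after a correction for GC content (adjusted p = 0.0434). That correction, chosen after seeing the data, left 31 calls, 27 of them among the 51. It ended those of miR-296-5p (log2 fold change 1.61 before and 1.25 after, adjusted p = 0.0506, and 7.14e-06 to 0.0506 over all settings on 4 libraries) and miR-328-3p (1.09 before and 0.70 after, adjusted p = 0.0677, and 1.42e-05 to 0.0677).

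**Figure D1:**
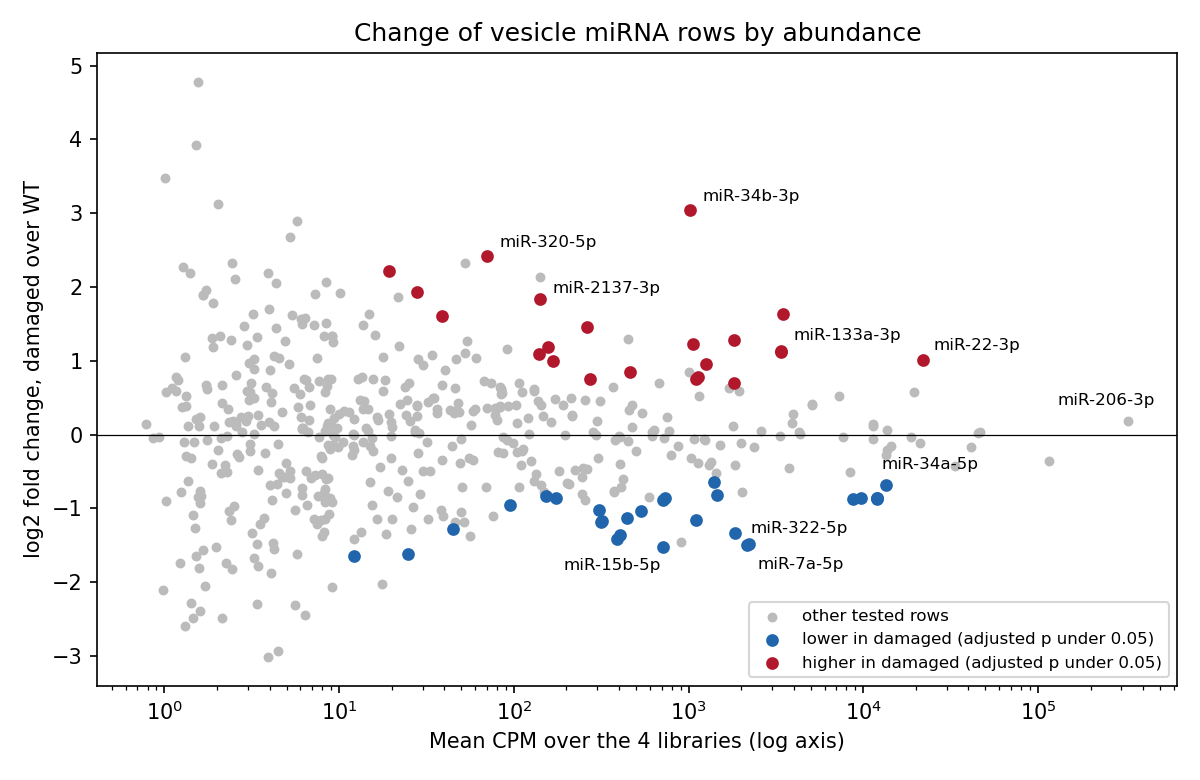
Each point is 1 of 522 tested rows, with the mean CPM over the 4 libraries on a log axis against the log2 fold change of damaged over WT; 14 rows with a count of 0 in both libraries of a group are not drawn. Red and blue points passed the edgeR test as higher and lower, and miR-34b-3p stands highest among them at 3.05.

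Among the lower rows, miR-15b-5p (UAGCAGCACAUCAUGGUUUACA), a regulator of cell cycle and survival genes in an intron of Smc4 on chromosome 3 at 69009775 to 69009796, fell from 1061 ± 35.1 to 370 ± 2.58 CPM (SD, n = 2). Its log2 fold change was -1.52 ± 0.12 (SE, adjusted p = 0.00914 by edgeR). The rows of miR-7a-5p, which share 1 sequence, lie in an intron of Hnrnpk on chromosome 13 and between genes on chromosome 7, and had log2 fold changes of -1.48 and -1.50. miR-25-3p, on chromosome 5 at 138165332 to 138165353 within Mcm7, a gene of DNA replication, fell from 1513 ± 8.30 to 681 ± 25.2 CPM (SD, n = 2). The mature sequences of miR-183-5p, miR-96-5p and miR-182-5p lie between 30165962 and 30169732 on chromosome 6, and had log2 fold changes of -1.35, -1.41 and -1.03. miR-322-5p and miR-351-5p, of 1 cluster on chromosome X, had -1.33 and -1.13. miR-196a-5p (Mir196a-2), in an intron of Hoxc5, fell from 12485 ± 142 to 6860 ± 852 CPM (SD, n = 2; adjusted p = 0.0248). miR-341-3p, of the Dlk1-Dio3 cluster, had 63 and 42 counts in WT and 0 in both damaged libraries, at least 23.3-fold lower with a floor of 3 counts per library, and at least 13.2-fold without WT replicate 1.

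**Figure D2:**
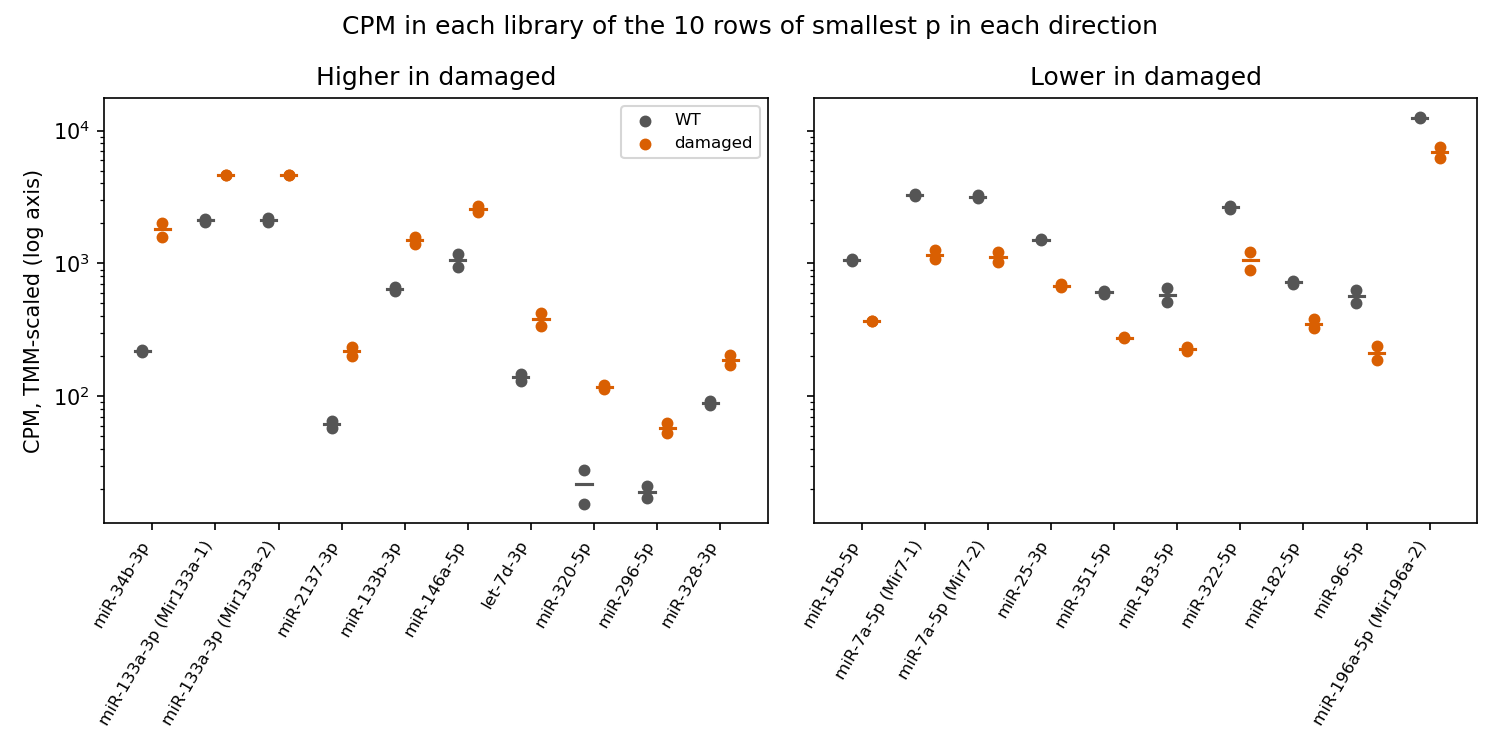
Points give the CPM of each library on a log axis for the 10 called rows of smallest p in each direction, with WT in grey, damaged in orange and short lines at the group means. By the rule that picked the rows, both damaged libraries lie on the same side of both WT libraries in each, as for miR-34b-3p with means of 219 and 1807 CPM.

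Muscle-enriched miRNAs were higher as a group at camera's preset correlation. They were not called with an estimated one, which with 2 residual degrees of freedom decides little. Of 13 tested rows, 3 rose, all of them miR-133 rows, and 10 did not pass. The median log2 fold change was 1.12, the value of the miR-133a-3p (Mir133a-2) row. Adjusted over the list alone, 7 rose and 1 fell. The rows that rose were the miR-133a-3p copies and miR-133b-3p. These sequences differ in the last base only, so reads may be counted for the wrong one. The 3 rows may thus hold 1 signal. miR-1a-3p, whose counted row is 1 of 2 identical gene copies, stood at 3557 ± 333 and 4317 ± 593 CPM (SD, n = 2; adjusted p = 0.262). miR-206-3p took 30.61% of all counts in WT and 35.25% in damaged, against 31.59% and 36.99% for the whole list. Its log2 fold change was 0.18 (adjusted p = 0.334 by edgeR). camera called the list (adjusted p = 0.00211), with adjusted p = 0.214 with an estimated correlation. The group moved beside entries suspected of being fragments of other RNA, whose share of counts was 0.226% ± 0.0697 in WT and 0.659% ± 0.0348 in damaged (SD, n = 2), and beside neural markers, which were higher (camera adjusted p = 0.0119, and adjusted p = 0.215 with an estimated correlation; 0.0514 without damaged replicate 1 and 0.0693 without WT replicate 1). Myogenic regulators, which steer myoblast growth and differentiation, went both ways: of 48 rows, both copies of miR-125b-5p rose, miR-322-5p, miR-351-5p and miR-497a-5p fell, and 43 did not pass. miR-497a-5p had a log2 fold change of -1.28 before and -1.30 after the GC correction, and its adjusted p went from 0.0411 to 0.0506. Adjusted over the list alone, 3 rose and 4 fell. The median of that list was 0.02, its mean -0.17 and the direction of camera downward, and camera did not call it (adjusted p = 0.813). Its most abundant members, miR-27b-3p and miR-23a-3p, had log2 fold changes of -0.42 (adjusted p = 0.124) and 0.58 (adjusted p = 0.0531).

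The X-linked cluster of miR-322 and miR-503, the miR-17 polycistron with its paralogs, the oncomiR list and the Sfmbt2 repeat cluster were lower as groups. This held at camera's preset correlation. None was called with an estimated one, which with 2 residual degrees of freedom decides little. In the X-linked cluster of miR-322 and miR-503, 4 of 13 rows fell, 9 did not pass, and the median was -1.05; adjusted over the list alone, 6 fell. Over all rows these were miR-322-5p, miR-351-5p and both copies of miR-450a-5p, and the latter went from -1.19 and -1.17 to -0.84 and -0.82 after the GC correction (adjusted p = 0.0622 and 0.0677). In the miR-17 polycistron with its paralogs, miR-25-3p and miR-93-5p fell among 18 rows, the median was -0.82, and 6 fell adjusted over the list alone. The most abundant member, miR-92a-3p (Mir92-1), had 2557 ± 412 CPM in WT and 1488 ± 246 CPM in damaged (SD, n = 2; adjusted p = 0.0531), and passed in 7 other settings on 4 libraries (lowest adjusted p = 1.2e-06). Of 36 oncomiR rows, 6 fell and none rose; adjusted over the list alone, 13 fell and 1 rose. The 6 were miR-183-5p, miR-182-5p, miR-96-5p, both copies of miR-196a-5p (the Mir196a-1 row at -0.87 before and -0.71 after the GC correction, adjusted p = 0.0504) and miR-210-3p, a hypoxia-induced miRNA, while miR-21a-5p had a log2 fold change of -0.35 (adjusted p = 0.331). camera called the 3 lists at adjusted p = 0.00211, 0.00273 and 0.00211 in that order, and adjusted p = 0.214 to 0.215 resulted with an estimated correlation. Of 42 rows of the Sfmbt2 repeat cluster, 3 fell, namely miR-669l-5p, miR-669m-5p (Mir669m-1) and miR-467e-5p at 125 ± 0.428 and 64.4 ± 7.06 CPM (SD, n = 2); adjusted over the list alone, none passed. After the GC correction these 3 had log2 fold changes of -1.37, -1.53 and -0.61 in place of -1.62, -1.64 and -0.96 (adjusted p = 0.0506, 0.0557 and 0.0877 in that order). The 42 rows stand for only 17 distinct mature miRNAs, and camera took copies of 1 miRNA as separate members, which can make its p too small. camera called that cluster (median -0.80, adjusted p = 4.82e-05), with adjusted p = 0.214 with an estimated correlation, and its near-identical copies leave single rows uncertain. These groups were lower in the libraries where the share of suspected fragments was 0.659% ± 0.0348 against 0.226% ± 0.0697 in WT (SD, n = 2) and where neural markers were higher (camera adjusted p = 0.0119, and adjusted p = 0.215 with an estimated correlation; 0.0514 without damaged replicate 1 and 0.0693 without WT replicate 1).

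The oxidative stress, p53 and hypoxia list held the strongest rise beside falls. miR-34b-3p rose, whereas miR-34a-5p, of the same family, fell from 16567 ± 464 to 10296 ± 476 CPM (SD, n = 2; log2 fold change -0.69, adjusted p = 0.0275). miR-210-3p fell with a log2 fold change of -0.86 (adjusted p = 0.0335), and miR-34c-3p had 0.85 (adjusted p = 0.0580). Of 16 rows, 13 did not pass, and adjusted over the list alone 3 rose and 3 fell. camera did not call the list (median 0.58, adjusted p = 0.120), although it did without damaged replicate 2 (adjusted p = 0.0314). Among 39 rows of tumour-suppressor miRNAs, miR-34b-3p rose and 5 fell, with miR-7a-5p and miR-218-5p, each in 2 copies, and miR-34a-5p as the lower ones; adjusted over the list alone, 2 rose and 5 fell (camera adjusted p = 0.593). Of 25 mesenchymal and fibroblast rows, miR-22-3p rose and 3 rows of miR-199a-3p and miR-199b-3p, which share 1 sequence, fell. After the GC correction the miR-218-5p rows went from -0.89 and -0.86 to -0.67 and -0.64 (adjusted p = 0.0555 and 0.0624) and the miR-199 rows from -0.86, -0.86 and -0.87 to -0.69, -0.70 and -0.71 (adjusted p = 0.0506 each). In the mesenchymal list, adjusted over the list alone, 4 rose and 9 fell (camera adjusted p = 0.319).

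The let-7 family, with 22.2% ± 0.368 of counts in WT and 22.1% ± 0.875 in damaged (SD, n = 2), had 1 riser, let-7d-3p, among 26 rows, also adjusted over the list alone (camera adjusted p = 0.390). let-7c-5p (Mirlet7c-2), the most abundant member, had a log2 fold change of 0.03 ± 0.10 (SE). In the miR-30 family no row of 10 passed, over all rows or adjusted over the list alone, and miR-30d-5p had 0.59 (adjusted p = 0.0544), passing in 5 other settings on 4 libraries (lowest adjusted p = 0.00044). camera gave adjusted p = 0.0988 for that family and 0.0339 without WT replicate 2. In the Dlk1-Dio3 cluster only miR-341-3p passed among 17 rows, also adjusted over the list alone, and the median was 0.01, also with miR-341-3p at its bound (camera adjusted p = 0.671), with miR-127-3p at 123 ± 17.5 and 123 ± 9.61 CPM (SD, n = 2). The mean of -0.67 there rests on the fitted value of miR-341-3p, which is no bound.

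Of the tested lists of other sources, camera called the neural list at its preset correlation but not with an estimated one (adjusted p = 0.215). It did not call the blood cell and liver list. Both lists were covered in part only. In the neural list 13 of 34 rows, those of miR-9 and miR-219a among them, shared bases with an opposite-strand entry and had 0 counts. In the blood cell and liver list this held for 5 of 19 rows, of miR-122, miR-142a and miR-486a. In the neural list, miR-212-3p, miR-132-5p and miR-128-3p (Mir128-1) rose among 11 rows, and adjusted over the list alone 6 rose. miR-212-3p and miR-132-5p lie in 1 cluster on chromosome 11, starting at 75173443 and 75173686. Whether these rows mark another cell source was not tested. camera called the list (median 0.64, adjusted p = 0.0119), with adjusted p = 0.215 with an estimated correlation, 0.0514 without damaged replicate 1 and 0.0693 without WT replicate 1. After the GC correction the 3 risers had log2 fold changes of 1.08, 1.06 and 0.88 in place of 1.19, 0.99 and 0.85, with adjusted p = 0.0506, 0.0504 and 0.0506. miR-128-3p did not pass with its identical copies summed (log2 fold change 0.78, adjusted p = 0.0690, the highest over all settings on 4 libraries, with 3.33e-05 the lowest). No row of the blood cell and liver list passed among 10, over all rows or adjusted over the list alone (median 0.13, camera adjusted p = 0.474). The medium held 10% bovine serum, and bovine miRNAs of identical sequence cannot be told apart from mouse ones. The most abundant rows of that list were miR-451a-5p at 1587 ± 137 and 1444 ± 81.3 CPM and miR-16-5p (Mir16-1) at 1506 ± 44.6 and 1165 ± 212 CPM (SD, n = 2). Of the epithelial markers only miR-375-3p and miR-200c-3p were tested, at 7.08 CPM or less per group mean, and neither passed. All 4 endothelial rows shared bases with an opposite-strand entry and had 0 counts, so that list was not tested. Of 11 entries suspected of being fragments of other RNA, miR-2137-3p, miR-6240-5p and miR-5121-3p rose, miR-5099-3p fell, and the median was 1.70; adjusted over the list alone, 7 rose and 1 fell. miR-6240-5p, the most abundant, had 1684 ± 745 CPM in WT and 5243 ± 289 CPM in damaged (SD, n = 2); after the GC correction its log2 fold change was 1.23 in place of 1.64 (adjusted p = 0.0677), and that of miR-5121-3p 2.25 in place of 2.22 (adjusted p = 0.0504). camera called these entries (adjusted p = 0.00147), with adjusted p = 0.214 with an estimated correlation.

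**Figure D3:**
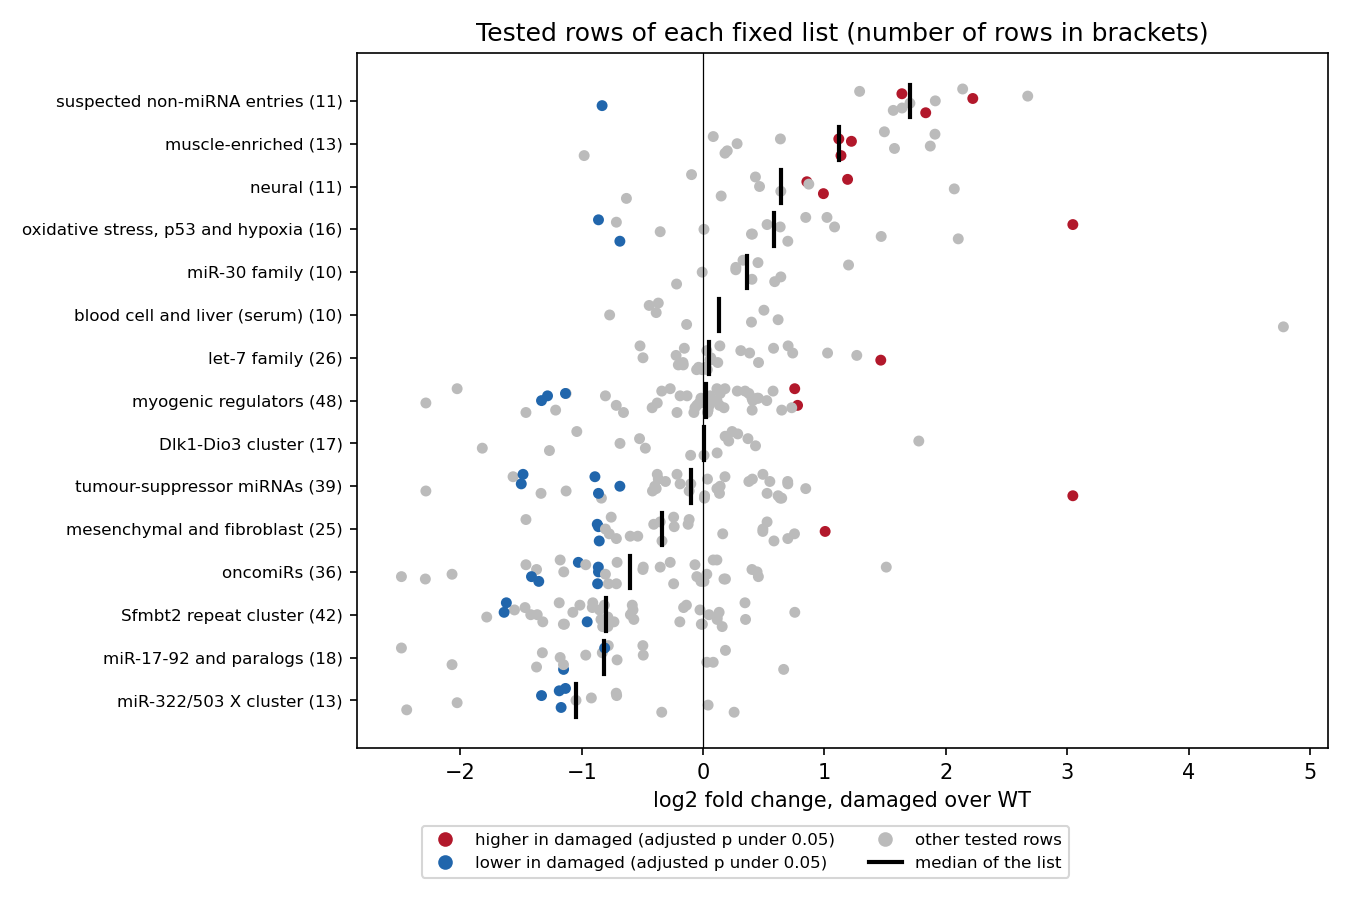
Points give the log2 fold change, damaged over WT, of the tested rows of each list with at least 3 of them, and black bars the medians; rows with a count of 0 in both libraries of a group are not drawn. Medians run from -1.05 for the X-linked cluster of miR-322 to 1.70 for entries suspected of being fragments of other RNA, and red and blue points passed the edgeR test.

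Libraries of 1 group resembled each other more than libraries of different groups. Across the 536 tested rows, which are not independent replicates, Pearson's r of log2 CPM was 0.964 between the WT libraries and 0.966 between the damaged libraries, against 0.931 to 0.951 between groups. The biological coefficient of variation was 34.9% over all tested rows and had a median of 14.8% for the 159 rows of at least 100 CPM.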

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

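The GC correction, the sum over identical sequences, and DESeq2 and limma-voom without 1 library were chosen after seeing the data. Against 51 rows called by edgeR, the count was 77 with upper-quartile scaling, 131 without a filter, 91 with at least 10 CPM in at least 2 libraries, 100 with DESeq2, 79 with limma-voom, 127 with the replicate number as a block and 31 after the GC correction; the cause was not tested. The other settings on 4 libraries gave 49 to 63. Without 1 library edgeR called 0 (without WT replicate 1, WT replicate 2 or damaged replicate 1; 103, 124 and 144 rows at an unadjusted p under 0.05) or 30 (without damaged replicate 2), DESeq2 59 to 75 and limma-voom 0 to 98 (0 without WT replicate 1 or 2, with 100 and 106 at an unadjusted p under 0.05), with the lone library assumed to vary like the others. Fewer samples account for part of this. Equal replicate numbers are not stated to mark pairs, and deviations of such libraries from their group means correlated at 0.00316 across rows, over 2 pairs.

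Of the 51 rows, 49 to 51 kept their call under the other scalings, 50 under DESeq2 and under limma-voom, and 27 after the GC correction. None that was fitted changed direction in any setting. Without 1 library this was nearly bound to result, as all 51 rows had both damaged libraries on the same side of both WT libraries. The other scalings moved the median of all rows by at most 0.0521, so they decide little about direction. Of the 26 named rows that passed, 21 kept their call in every setting on 4 libraries; miR-128-3p (Mir128-1), miR-296-5p, miR-328-3p, miR-467e-5p and miR-6240-5p did not. Of the 23 named rows that did not pass, 8 passed in at least 1 such setting: miR-6236-3p in 11, miR-92a-3p (Mir92-1) in 7, miR-23a-3p and miR-30d-5p in 5 each, miR-467c-5p in 4, miR-128-3p (Mir128-2) in 3, miR-27b-3p in 2 and miR-21a-5p in 1. The number of lists called was 7, 9 with fry, 6 to 8 without 1 library and 0 of 15 with camera at an estimated correlation. That estimate gave the 7 lists adjusted p = 0.214 (muscle-enriched, miR-17 polycistron, oncomiR, Sfmbt2 and suspected entries) or 0.215 (neural, miR-322 cluster). With 2 residual degrees of freedom it had little power, so these values decide little. fry, which does not compare a list with other rows, called the blood cell and liver list (adjusted p = 0.034) and the oxidative stress, p53 and hypoxia list (adjusted p = 0.0253). Without 1 library, camera's adjusted p ran from 0.023 to 0.0693 for the neural list, 0.0339 to 0.806 for the miR-30 family and 0.0314 to 0.421 for the oxidative stress, p53 and hypoxia list; the cause was not tested. Leaving out 1 library does not test shares of counts, since with 2 libraries per group the shift cannot exceed the spread between replicates. With suspected and repeat entries left out of the total, the shares of the lists moved by no more than that spread. This decides little, as the suspected entries held only 0.226% of counts in WT and 0.659% in damaged. The mean gap between within-group and between-group Pearson's r was 0.0246, and 0.0269 with the stricter filter. Changes in rows of low count were recovered less often: simulated 2-fold changes were recovered for 41% of changed rows and 89.7% of those above 100 CPM. Depth was not varied there, so its part was not tested.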

Other observations

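The tests of the gap between suspected entries and other rows, of opposite-strand overlap, of miR-1a-3p, of genomic clusters and of hairpin arms were chosen after the values had been seen, as were the GC correction and the comparison of folds before and after it. The sorting motifs were chosen without a look at their values. The items named here were chosen after their values were seen.

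Neighbouring hairpins tended to change alike. Over 17 clusters within 10000 bases, with 43 miRNAs of at least 100 CPM and 1 arm per hairpin, the mean within-cluster SD of log2 fold changes was 0.456, against 0.622 in shuffles over 105 miRNAs (permutation p = 0.038, one-sided, Benjamini-Hochberg adjusted p = 0.038 over 3 hypotheses). Another version of the test, run later, shuffled the 43 clustered miRNAs alone (permutation p = 0.0026), and the first version is the one counted here. Shared transcription of a cluster is a candidate explanation. Several clusters held members that moved apart. miR-34b-3p had a log2 fold change of 3.07 and miR-34c-3p 0.87, miR-133b-3p 1.24 and miR-206-3p 0.20, and miR-125a-5p 0.97 and let-7e-5p -0.15, the first of each pair past the threshold and the second not. The sequence of miR-133b-3p differs from that of miR-133a-3p, of other loci, in the last base only. Its row may therefore hold reads from those loci. In a pair of paralogous clusters miR-23a-3p and miR-23b-3p had log2 fold changes of 0.59 and 0.54, and their neighbours miR-27a-3p and miR-27b-3p had -0.25 and -0.40, none past the threshold.

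The arms of 61 hairpins also moved together in part, which may reflect their shared precursor. Across hairpins, which are not independent replicates, Pearson's r between the log2 fold changes of the arms was 0.31 (permutation p = 0.015, two-sided, Benjamini-Hochberg adjusted p = 0.023) and Spearman's rho 0.315 (permutation p = 0.014). In 15 hairpins the arms differed by edgeR's diffSpliceDGE at an adjusted p under 0.05. Rows of identical sequence were summed here, so an arm with several gene copies holds the reads of all of them. In let-7d the 3p arm had 1.48 and the 5p arm -0.04 (adjusted p = 0.00251), and in miR-34b 3.07 and 0.41 (adjusted p = 0.00251). For miR-125b-1 the 5p value of 0.78 pools the identical copies of Mir125b-1 and Mir125b-2. The 3p arm of Mir125b-1 had -0.64 (adjusted p = 0.00345), so a change at the other locus could also give this difference.

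Sorting motifs gave no separable result. The 45 miRNAs with GGAG or CCCU, short motifs tied to vesicle loading, had a median log2 fold change 0.325 above that of 230 others (permutation p = 0.01, two-sided, Benjamini-Hochberg adjusted p = 0.023). They also had more G and C (55.5% against 46.7%), and after the GC correction the difference was 0.139 (permutation p = 0.28), so a GC trend between libraries may account for it.

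Entries suspected of being fragments of other RNA were higher in damaged, with a median log2 fold change of 1.70 over 11 rows. Of these rows 3 passed as higher and 1, miR-5099-3p, as lower, and camera did not call the list with an estimated correlation (adjusted p = 0.214). Under 3 other scalings the lowest median was 1.66, which decides nothing, as they moved the median of all rows by at most 0.0521. A factor per library shared by all rows is argued against by the gap to the other tested rows, 1.70 with an SE across rows of 0.338, which such a factor would leave at 0. After the GC correction the median was 1.44 with an SE of 0.369, against a bound of 1. Both SEs are across the 11 rows, which come from the same 4 libraries, and do not cover the spread between libraries. Across these rows, but not across libraries, the values argue narrowly against a GC trend as the whole cause. miR-6240-5p lost its call with a log2 fold change of 1.23 ± 0.31 in place of 1.64 ± 0.31 (SE). More fragments of other RNA in vesicles of treated cells, or in those preparations, stay open and untested.

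Rows that share bases with an opposite-strand entry were at 0 in all 4 libraries in 105 of 106 cases, against 1004 of 2004 other rows (Fisher's exact test, two-sided, p = 2.22e-29). Such rows come in opposite-strand pairs and are not independent of each other, so this p is too small. Reads that overlap 2 entries and were left uncounted are a candidate explanation, since the counting command held neither a strand option nor an overlap option. Absence from the vesicles is excluded for miR-1a-3p: its Mir1a-2 row was 0, while the Mir1a-1 row with the identical sequence held at least 17122 counts in every library. For miR-24-3p, at 0 in both copies beside abundant neighbours miR-23a-3p and miR-27b-3p, and for miR-126a, the values stay open. As miR-1a-3p shows, a count of 0 in such a row does not show absence.

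Called rows that were higher had more G and C (54.4% ± 10.6, SD, n = 22 rows) than called rows that were lower (43.7% ± 9.17, SD, n = 29 rows). After the GC correction 27 of the 51 rows kept their call, above the bound of 25.5 set beforehand against a GC trend as the cause, but within a counting spread of 3.6. That spread, like the SE for the suspected entries, was added to the rule after the count of 27 was seen; without it, the count would have spoken against the trend. Of the 24 others, 4 (miR-128-3p, miR-497a-5p, miR-132-5p and miR-5121-3p) had a fold at least as large after the correction and 6 a fold smaller by no more than 1 SE; the 4 lost their calls as the highest unadjusted p that passed went from 0.00437 to 0.00267, with a median p of 0.00345 before and 0.00355 after, so the values give no sign of a GC trend behind them. For the 14 lost rows whose fold shrank by more than 1 SE, and 8 of the 27 kept rows that shrank as much (both copies of miR-7a-5p and miR-133a-3p, miR-15b-5p, miR-96-5p, miR-196a-5p (Mir196a-2) and miR-2137-3p), a GC trend stays open as part of the cause, since it and the treatment separate the same libraries.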
